A study of Mus musculus with 9 samples.

How the data were processed

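Low-input RNA sequencing was done on haematopoietic stem cells (HSCs) sorted from bone marrow of wild-type mice, in 9 libraries of 3 groups: young HSC, old HSC, and old HSC with the sphingosine kinase 2 inhibitor ABC294640, with 3 replicates each. Per the labels' protocols, marrow came from femora and tibiae, red cells were lysed, 1500 cells were sorted per library, complementary DNA was made from polyadenylated RNA by a modified full-length low-input protocol with 12 cycles of PCR, libraries were made with a transposase kit, and paired-end reads were sequenced. The protocols give ages of 2 to 4 or 20 to 24 months, assigned here to the young and old groups by their wording. The groups and replicate numbers were taken from the sample labels. The sort markers, and the route, dose and duration of the inhibitor, are not given in the sources used here.

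The deposited table holds an estimated count of reads per gene and library, that is, expected counts that need not be whole. Per the submitters' processing notes, Trim Galore 0.6.2, STAR 2.6.1d, HTSeq 0.10.0, edgeR 3.24.3 and the genome build mm10 were used by the authors, with no role or order stated. Of the non-zero values 56.0% were whole, which is why the deposited values were taken to be expected counts and rounded to whole numbers before testing. The step that gave the fractional values is not given in the sources used here. Nothing states that strand was used in counting, and a transposase kit does not mark strand, so overlapping genes cannot be told apart. All 23317 rows matched a gene identifier of GENCODE mouse release 21 (GRCm38), 21369 with the same symbol, 20556 of them protein coding and 2193 pseudogenes. Coordinates are from that annotation and GRCm38.

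Library totals ran from 16663445 to 23254115 counts. Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, its default filter by group (14227 genes kept) and the quasi-likelihood test in 1 fit of all 9 libraries with group as the only term. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are CPM, from library sizes scaled by TMM. A level of 0 in a group was given a floor of 3 counts over the group, and folds against it and such floors cover counting error only, since reads from amplified DNA without molecular identifiers are not independent molecules. Between 37 fixed gene lists and the other genes, camera of limma 3.58.1 was run with a preset correlation of 0.01, for the 36 lists with at least 5 tested members. It was run again with the correlation estimated from the data, and fry tested whether the genes of a list moved 1 way on balance. The members of each list were also adjusted over the list alone. Library measures were compared by two-sided exact permutation tests. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

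The groups, comparisons, tests, gene lists, rule for named genes and the first set of other settings below were fixed before the data were examined. The rule named, for old against young HSC and for treated against untreated old HSC, (a) the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 10 CPM in the higher group, libraries that did not overlap between groups, and a symbol not of a predicted gene or pseudogene (Gm and digits, Rik or -ps), which let through Rps3a2 and Rpl37rt, annotated as processed pseudogenes; (b) up to 4 members of smallest p of each fixed list described; (c) Sphk1, Sphk2, Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Procr, Slamf1, Vwf, Selp and Cdkn1a; and (d) up to 6 genes past the threshold in both comparisons with opposite sign, by the smaller of their changes. For treated old against young HSC it named 4 rises and 4 falls, and (c). Which of the lists are described with members, and their order, was chosen after the list results were seen. Some results that the rule named are not reported here.

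The first set of other settings was RLE size factors, DESeq2 1.42.0, no filter, a stricter filter (at least 5 CPM in at least 3 libraries), a fit of the 2 groups alone, the replicate number as a block, leaving out each library in turn, a threshold on the fold change, the estimated correlation, and fry. Chosen after seeing the data were leaving out immunoglobulin and T cell receptor genes, genes with shared words, and sex chromosome genes, thinning to 16663445 counts per library, and removing trends on GC content and transcript length, for which 99.9% of genes had a value. A gene was counted as having shared words where at least 20% of its 31-base words occur in another gene's transcripts. The comparison of the age effect with the inhibitor effect was set against 20 simulations with no effect and the same shared old libraries, and the same draws were analysed under 8 of the other settings, chosen after seeing the data.

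The tests were run on simulated counts of 14227 genes with some genes changed by known folds. For old against young HSC, edgeR recovered 49.3%, 59.7% and 86.4% of genes changed 1.25-fold, 1.5-fold and 2-fold, with 9 false calls of 155. For treated against old HSC it recovered 31.3%, 67.2% and 68.2%, with 8 false calls of 130. The last value missed a bound of 70% set at first. The bound was then replaced by recovery of over 90% among 2-fold genes at 5 CPM or more, of which 100% were recovered in both simulations, and by fitted folds close to the simulated ones.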

Results

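Cells labelled as haematopoietic stem cells (HSCs) were profiled by low-input RNA sequencing in 3 groups of 3 libraries. HSCs are the bone marrow cells from which all blood lineages arise. The groups were HSCs of young mice, HSCs of old mice, and HSCs of old mice with ABC294640, which the submitters describe as an inhibitor of sphingosine kinase 2 (SphK2), an enzyme that phosphorylates sphingosine to sphingosine 1-phosphate. How, at which dose and for how long the inhibitor was given, and which surface markers defined the sorted cells, is not given in the sources used here. The title of the study places it around blocking sphingosine metabolism, ferroptosis (iron-dependent cell death by lipid peroxidation) and the rejuvenation of old HSCs. The mice were wild type. Each library was made from 1500 sorted cells. The total per library ran from 16663445 to 23254115 counts, and the common biological coefficient of variation over all 9 libraries was 0.0583. No label says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Over immunoglobulin variable genes with at least 20 counts in a pair of libraries (20 to 84 genes a pair), the highest chi-square per degree of freedom was 1.89 between libraries of a group and the lowest was 8.79 between groups. Unless stated otherwise, levels are CPM, counts scaled by library size, as mean ± SD (n = 3), log2 fold changes carry their standard error, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14227 genes.

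For most measures of library make-up, the 3 young and the 3 old libraries did not overlap. Transcripts of the granule protein genes Mpo, Elane and Prtn3, a trio chosen after the values were seen, held 2.80% ± 0.191 of the counts in young HSC, 3.93% ± 0.0910 in old HSC and 3.74% ± 0.0516 in treated old HSC. Immunoglobulin genes, whose transcripts are made by B cells and plasma cells, held 0.0503% ± 0.00291, 0.138% ± 0.00805 and 0.125% ± 0.00435. Cytosolic ribosomal protein genes held 9.37% ± 0.157, 8.10% ± 0.321 and 8.67% ± 0.0814, and pseudogenes 1.53% ± 0.0360, 1.14% ± 0.0682 and 1.29% ± 0.0397. The mitochondrial genome held 6.11% ± 0.306, 5.60% ± 0.124 and 5.73% ± 0.173, and haemoglobin genes held 0.00303% ± 0.000306, 0.00237% ± 0.000306 and 0.00230% ± 0.000100. The 10 most abundant genes held 9.99% ± 0.117, 10.5% ± 0.152 and 10.4% ± 0.143. Young libraries detected 20221 ± 63.5 genes, old libraries 18643 ± 489 and treated libraries 18687 ± 288. With counts thinned to 16663445 per library these numbers were 19918 ± 30.1, 18495 ± 295 and 18538 ± 135. Two-sided exact permutation tests of 3 against 3 libraries cannot go below p = 0.1. That value was reached between young and old HSC for all of these measures except the haemoglobin share (exact p = 0.2).

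**Figure D1:**
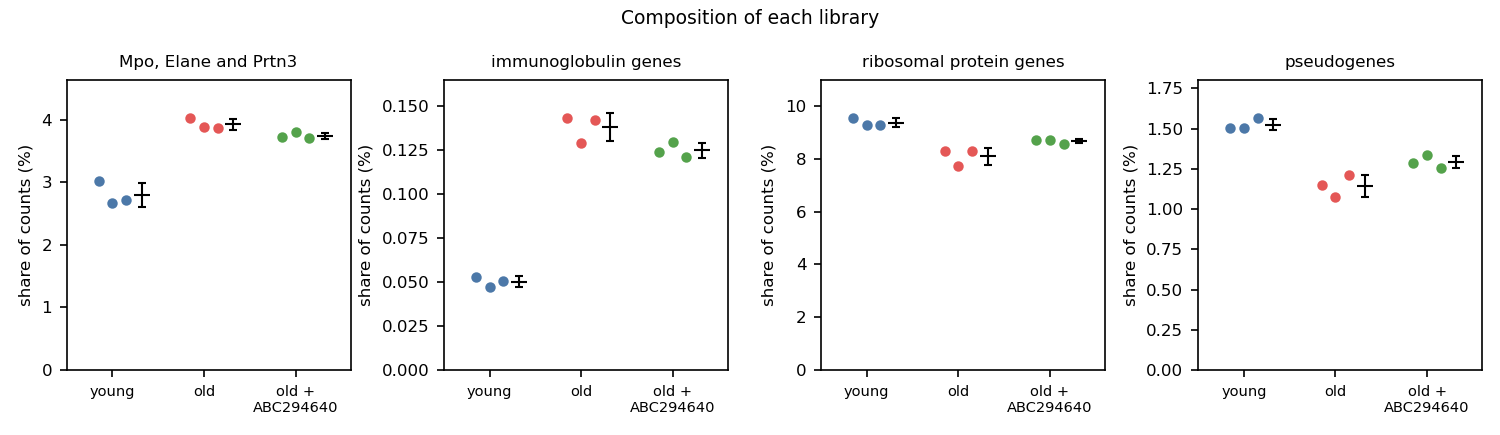
Share of all counts (percent) held by Mpo, Elane and Prtn3, by immunoglobulin genes, by cytosolic ribosomal protein genes and by pseudogenes; points are the 9 libraries and the bar is the mean ± SD of 3. The immunoglobulin share had a mean of 0.0503% in young HSC and 0.138% in old HSC, and the ribosomal protein share was lowest in old HSC (8.10%).

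The comparison of old with young HSC asks what differs with age. Interferon-stimulated genes and erythroid and megakaryocyte genes were lower in old HSC, and genes of granulocytes, mitosis, the unfolded protein response, glycolysis and iron handling were higher. The granulocyte and glycolysis calls were lost with an estimated correlation (adjusted p = 0.0893 and 0.111). Rtp4, an interferon-induced chaperone gene, fell from 72 ± 4.55 to 27.8 ± 1.71 CPM (2.59-fold), and Car1, an erythroid carbonic anhydrase, fell from 727 ± 28.8 to 313 ± 2.34 CPM (2.32-fold). Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose from 91.5 ± 3.13 to 216 ± 6.54 CPM (2.36-fold), and the chaperone gene Hspa5 rose from 902 ± 42.6 to 1507 ± 51.6 CPM (1.67-fold). Lcn2 is a member of both the granulocyte and the iron handling lists, so these calls are not independent. The Y-linked genes Ddx3y and Eif2s3y were higher in every old library than in any young one, so that age and the apparent sex of the donors differed together. In all, 2788 genes rose and 2818 fell of 14227 tested, with a median absolute log2 fold change of 0.43 among them.

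Among genes at 10 CPM or more with libraries that did not overlap and symbols not in the style of predicted genes or pseudogenes, the largest rises and falls were taken. The 6 rises included the Y-linked helicase gene Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629 in GRCm38), from 0.936 ± 0.258 to 38.9 ± 5.08 CPM (log2 fold change 5.39 ± 0.17, adjusted p = 1.81e-15), and Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847), from 2.55 ± 0.848 to 78.1 ± 2.92 CPM (log2 fold change 4.95 ± 0.12, adjusted p = 6.28e-17). The other 4 were immunoglobulin kappa variable genes. Igkv15-103 had no count in young HSC and 10.8 ± 0.897 CPM in old HSC, at least 229-fold higher against a floor of 3 counts over the group, which covers counting error only. Igkv10-96 rose from 0.0317 ± 0.0275 to 13.8 ± 1.32 CPM, Igkv1-110 from 0.0307 ± 0.0532 to 12 ± 0.985 CPM and Igkv12-46 from 0.164 ± 0.114 to 20.7 ± 0.991 CPM. The 6 falls included a further trio of kappa variable genes, Igkv8-19 (from 12.9 ± 0.149 to 0.0356 ± 0.0313 CPM), Igkv2-137 (from 10.7 ± 0.339 to 1.13 ± 0.364 CPM) and Igkv19-93 (from 20.5 ± 2.82 to 4.28 ± 0.176 CPM). H2-Eb1, a major histocompatibility complex class II gene (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674), fell from 51.8 ± 1.38 to 13.5 ± 1.39 CPM (log2 fold change -1.95 ± 0.088, adjusted p = 4.55e-13). Rps3a2, a processed pseudogene in the annotation, fell from 395 ± 23.3 to 91.6 ± 0.33 CPM (log2 fold change -2.11 ± 0.055, adjusted p = 1.38e-16) and Hmga1b fell from 54.7 ± 6.79 to 14.2 ± 1.8 CPM (log2 fold change -1.95 ± 0.12, adjusted p = 6.12e-11). Rps3a2 and Hmga1b share 92.9% and 90.5% of their 31-base words with other genes, as do 48.0% to 63.6% of the words of all these kappa genes except Igkv15-103 and Igkv19-93, so that their counts are uncertain. Of all genes tested, 48.4% had 3 old libraries that did not overlap the 3 young ones, against 10% by chance.

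Interferon-stimulated genes fell as a group. Of 40 tested, 0 rose and 35 fell (0 and 36 adjusted over the list alone), with camera adjusted p = 5.35e-31. With Rtp4 (-1.37 ± 0.076, adjusted p = 1.14e-11) they included Ifi27l2a (-1.87 ± 0.10, adjusted p = 1.37e-11), the nucleic acid sensor Zbp1 (-1.63 ± 0.094, adjusted p = 1.95e-11) and the GTPase gene Igtp (-1.05 ± 0.062, adjusted p = 2.98e-11). Igtp overlaps Irgm2 on the same strand, and reads of the pair cannot be told apart by position alone. Of the erythroid markers, 3 rose and 20 fell of 25 tested (3 and 21 adjusted over the list alone), with camera adjusted p = 5.27e-11. Car1 (-1.21 ± 0.042, adjusted p = 7.27e-15), Car2 (-0.58 ± 0.037, adjusted p = 1.17e-10), the erythroid transcription factor gene Klf1 (-1.16 ± 0.074, adjusted p = 1.02e-10) and the blood group gene Rhd (-1.15 ± 0.092, adjusted p = 3.34e-09) fell, where 21.4% of the words of Car1 recur in other genes. Of the megakaryocyte and platelet markers, 1 rose and 16 fell of 27 tested (1 and 17 adjusted over the list alone), with camera adjusted p = 0.000125. The platelet chemokine gene Pf4 fell from 375 ± 16.6 to 178 ± 13 CPM (2.11-fold), F2rl2 fell from 33.8 ± 1.13 to 18.8 ± 0.96 CPM and Gfi1b from 87.6 ± 7.3 to 58.6 ± 3.17 CPM, and the member that rose was Clu, which encodes the secreted chaperone clusterin, from 21 ± 3.22 to 74.4 ± 5.04 CPM (3.52-fold). The interferon, erythroid and megakaryocyte calls held with an estimated correlation (adjusted p = 0.000294, 0.00447 and 0.0257). Mast cell and basophil markers fell too. Of 12 tested, 1 rose and 9 fell (1 and 10 adjusted over the list alone), with camera adjusted p = 0.0297, and adjusted p = 0.109 with an estimated correlation. That call ended with a stricter filter (adjusted p = 0.0548) and without old replicate 2 (0.0507).

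Granulocyte and monocyte markers rose as a group. Of 31 tested, 19 rose and 5 fell (19 and 5 adjusted over the list alone), with camera adjusted p = 3.39e-12, and adjusted p = 0.0893 with an estimated correlation. S100a8, which encodes a calcium-binding protein of neutrophils, rose from 2211 ± 50 to 4526 ± 354 CPM (2.05-fold), Chil3 from 169 ± 10.6 to 345 ± 10.1 CPM, Wfdc21 from 134 ± 5.84 to 316 ± 30.6 CPM and Lcn2 as given above. The count of Chil3 is uncertain, since 44.8% of its words recur in other genes. The share of counts in Mpo, Elane and Prtn3 beside them was 2.80% in young and 3.93% in old HSC. B cell markers went both ways, 4 rose and 5 fell of 17 tested (4 and 5 adjusted over the list alone). The 4 that rose included the light chain constant genes Igkc (from 165 ± 11.7 to 533 ± 46 CPM) and Iglc2 (from 2.65 ± 0.25 to 21.7 ± 0.457 CPM) and Jchain (from 30.1 ± 0.265 to 67.5 ± 3.94 CPM), which joins secreted antibodies and marks plasma cells, while the heavy chain gene Ighm, of naive B cells, fell from 95.7 ± 6.71 to 60.6 ± 0.763 CPM. For this list the median log2 fold change was -0.10, the mean 0.22 and the test upward (camera adjusted p = 0.008, and adjusted p = 0.138 with an estimated correlation). The call ended without immunoglobulin genes, a choice made after seeing the data (adjusted p = 0.503). T and NK cell markers did not pass. Of 15 tested, 3 rose and 5 fell (3 and 7 adjusted over the list alone), with camera adjusted p = 0.38. Stromal and endothelial markers did not pass either. Of 21 tested, 1 rose and 8 fell (1 and 8 adjusted over the list alone), with camera adjusted p = 0.0814.

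Genes of mitosis, the unfolded protein and integrated stress response and glycolysis rose, the last not past the threshold with an estimated correlation (adjusted p = 0.111). Of the mitosis genes, 22 rose and 1 fell of 32 tested (23 and 1 adjusted over the list alone), with camera adjusted p = 1.27e-05, and adjusted p = 0.0151 with an estimated correlation. Cyclin B1 (Ccnb1) rose from 277 ± 5.67 to 397 ± 3.54 CPM, Ccnb2 from 226 ± 3.87 to 282 ± 7.03 CPM, the kinase gene Aurka from 89 ± 3.79 to 122 ± 1.84 CPM and the kinesin gene Kif20a from 49.6 ± 2.25 to 67.9 ± 1.45 CPM. Ccnb1 and Kif20a share 46.9% and 29.1% of their words with other genes, so that their counts are uncertain. Genes of S phase and DNA replication did not pass as a list. Of 34 tested, 8 rose and 4 fell (8 and 4 adjusted over the list alone), with camera adjusted p = 0.237. CDK inhibitors and G1 cyclins did not pass either. Of 13 tested, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with camera adjusted p = 0.344. The unfolded protein and integrated stress response rose. Of 35 tested, 23 rose and 1 fell (23 and 1 adjusted over the list alone), with camera adjusted p = 1.17e-08, and adjusted p = 0.00781 with an estimated correlation. Hspa5 (0.74 ± 0.044, adjusted p = 3.29e-11), Xbp1, a transcription factor of the response (0.84 ± 0.044, adjusted p = 5.48e-12), Herpud1 (0.62 ± 0.048, adjusted p = 2.31e-09) and Cebpb (1.21 ± 0.068, adjusted p = 1.37e-11) all rose. Glycolysis genes rose. Of 22 tested, 14 rose and 0 fell (14 and 2 adjusted over the list alone), with camera adjusted p = 8.69e-08, and adjusted p = 0.111 with an estimated correlation. Gapdh rose from 981 ± 48.1 to 2376 ± 89.3 CPM (2.42-fold), Eno1 from 731 ± 10.6 to 1272 ± 39.1 CPM, Ldha from 1490 ± 38.7 to 1994 ± 45 CPM and Pgam1 from 416 ± 5.46 to 579.8 ± 23.8 CPM, and these 4 genes share 31.8% to 73.0% of their words with other genes, mostly copies that make their counts uncertain. Immediate early genes rose. Of 27 tested, 18 rose and 3 fell (19 and 3 adjusted over the list alone), with camera adjusted p = 6.99e-06, and adjusted p = 0.0893 with an estimated correlation. Those that rose included Sgk1 (1.13 ± 0.067, adjusted p = 3.6e-11), Egr1 (0.67 ± 0.041, adjusted p = 4.57e-11), Zfp36 (0.50 ± 0.043, adjusted p = 1.17e-08) and Jund (0.51 ± 0.058, adjusted p = 6.71e-07), which shares 31.3% of its words with other genes.

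Lysosome and autophagy genes rose. Of 43 tested, 22 rose and 5 fell (23 and 5 adjusted over the list alone), with camera adjusted p = 0.000228, and adjusted p = 0.0924 with an estimated correlation. Cd63 rose from 254 ± 7.14 to 518 ± 10.8 CPM (2.04-fold), the proton pump gene Atp6v1a from 56.7 ± 3.35 to 90.7 ± 0.688 CPM, Lamp2 from 215 ± 8.28 to 307 ± 7.54 CPM and the sialidase gene Neu1 from 18.9 ± 2.12 to 37.3 ± 2.68 CPM. Proteasome genes rose. Of 31 tested, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with camera adjusted p = 0.008, and adjusted p = 0.118 with an estimated correlation. NF-kB and inflammatory genes rose. Of 35 tested, 12 rose and 6 fell (12 and 6 adjusted over the list alone), with camera adjusted p = 0.008, and adjusted p = 0.0924 with an estimated correlation. Cholesterol and fatty acid synthesis genes rose. Of 29 tested, 13 rose and 4 fell (13 and 4 adjusted over the list alone), with camera adjusted p = 0.0354, and adjusted p = 0.126 with an estimated correlation. Cytosolic ribosomal protein genes fell. Of 76 tested, 6 rose and 47 fell (6 and 48 adjusted over the list alone), with camera adjusted p = 0.00159, and adjusted p = 0.482 with an estimated correlation. Rpl35 (-0.27 ± 0.039), Rpl37 (-0.37 ± 0.062) and Rpl37a (-0.30 ± 0.05) fell on the log2 scale and Rpl27 rose (0.34 ± 0.048), and 30.4% to 99.0% of the words of these genes recur in other genes. The stricter filter ended the calls of the proteasome (adjusted p = 0.154) and cholesterol lists (0.239). The cholesterol call also ended without sex chromosome genes (0.0523) and with counts thinned to equal depth (0.0532), settings chosen after seeing the data.

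**Figure D2:**
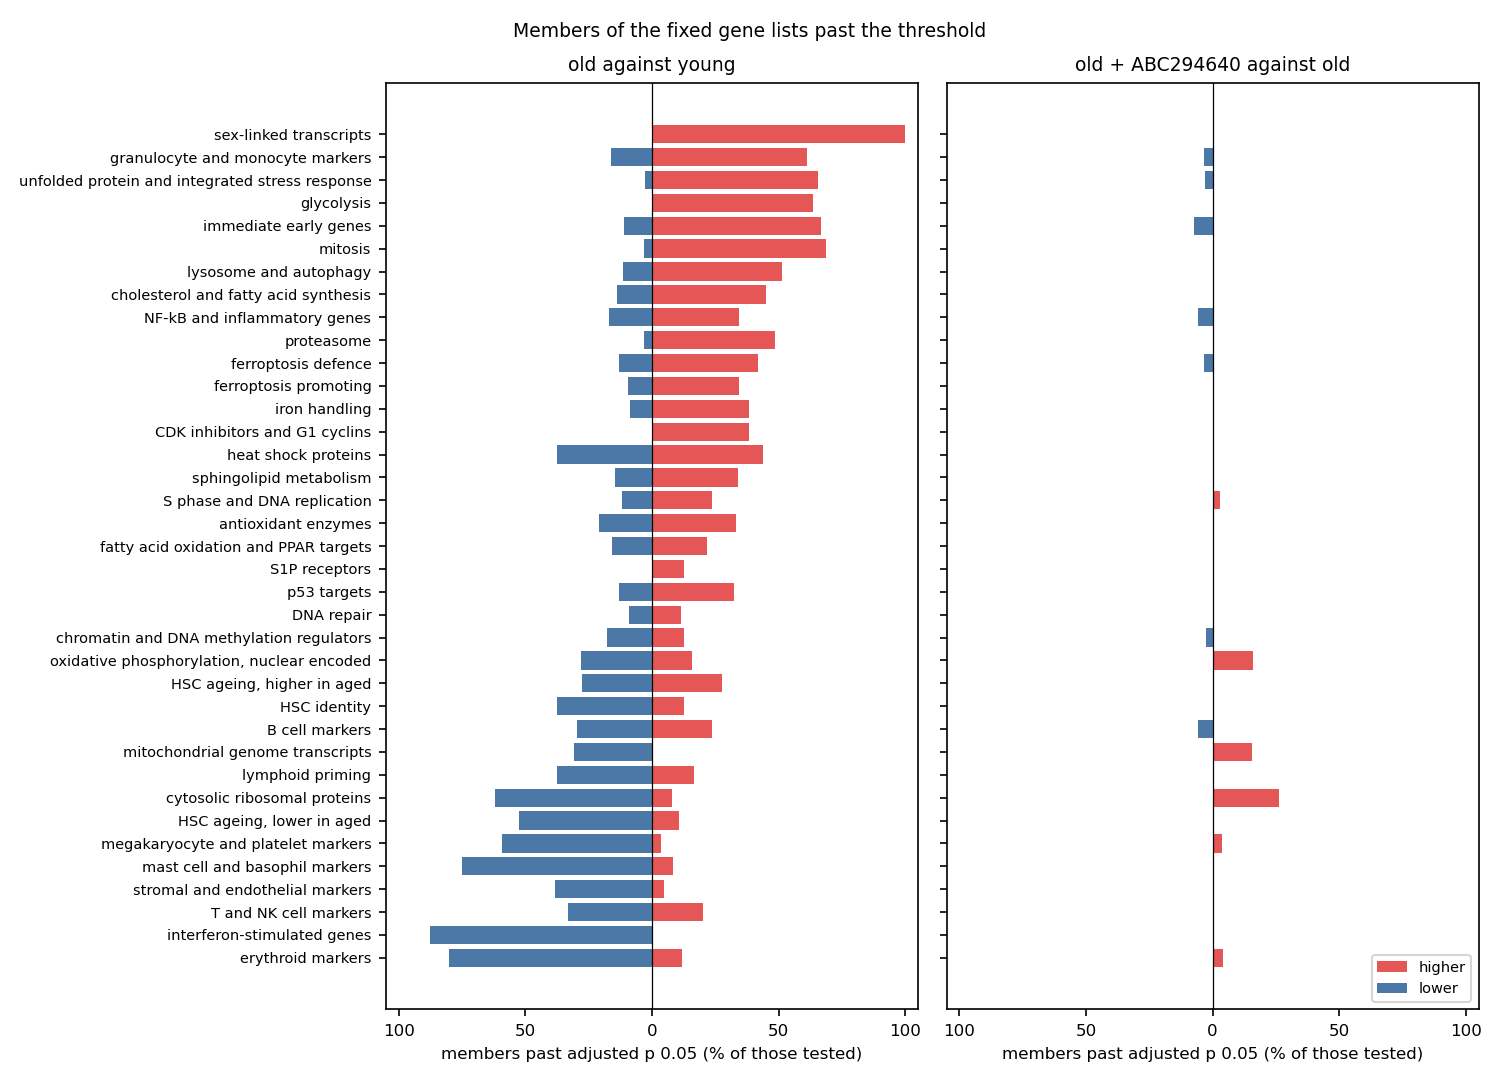
Percent of the tested members of each fixed gene list past the threshold, higher to the right and lower to the left, for each comparison, with lists ordered by the median log2 fold change with age. With age, 35 of 40 interferon-stimulated genes lay on the lower side and 23 of 35 unfolded protein and integrated stress response genes on the higher side.

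Iron and ferroptosis genes rose more often than they fell. The iron handling list shares Tfrc, Ncoa4 and other members with the ferroptosis promoting list, and Slc40a1, Fth1 and others with the defence list. The calls of these lists are therefore not independent. Of the iron handling genes, 13 rose and 3 fell of 34 tested (13 and 4 adjusted over the list alone), with camera adjusted p = 0.000711, and adjusted p = 0.0393 with an estimated correlation. Alas1, the first enzyme of haem synthesis, rose from 312 ± 10.8 to 572 ± 7.67 CPM, the iron exporter gene Slc40a1 rose from 26 ± 1.79 to 63.9 ± 4.25 CPM (2.46-fold) and Ncoa4, a receptor for ferritin breakdown, rose from 148 ± 4.17 to 225 ± 5.33 CPM. Of the genes of ferroptosis defence, 13 rose and 4 fell of 31 tested (13 and 4 adjusted over the list alone), with camera adjusted p = 0.0237, and adjusted p = 0.0924 with an estimated correlation. The glutathione enzyme genes Gsr (0.92 ± 0.048, adjusted p = 3.94e-12) and Gclm (0.66 ± 0.045, adjusted p = 2.81e-10) rose, whereas Slc7a11, the cystine importer, fell from 25 ± 2.25 to 15 ± 1.38 CPM (log2 fold change -0.73 ± 0.097, adjusted p = 5.17e-06). Of the ferroptosis promoting genes, 11 rose and 3 fell of 32 tested (11 and 3 adjusted over the list alone), with camera adjusted p = 0.008, and adjusted p = 0.119 with an estimated correlation. The transferrin receptor gene Tfrc rose from 37.4 ± 2.69 to 63.5 ± 5.05 CPM (log2 fold change 0.77 ± 0.071, adjusted p = 3.37e-08), as did the oxidase gene Cybb (0.77 ± 0.049, adjusted p = 9.53e-11) and the fatty acid elongase gene Elovl5 (0.48 ± 0.044, adjusted p = 2.92e-08). Of the sphingolipid metabolism genes, 14 rose and 6 fell of 41 tested (14 and 6 adjusted over the list alone), with camera adjusted p = 0.0343, and adjusted p = 0.0941 with an estimated correlation. Degs2, a sphingolipid desaturase and hydroxylase gene, rose from 2.32 ± 0.698 to 17.1 ± 0.899 CPM (7.33-fold), the sphingomyelin synthase gene Sgms2 from 57.1 ± 3.83 to 125 ± 4.7 CPM, the ceramide synthase gene Cers2 from 176 ± 1.66 to 245 ± 2.78 CPM and Sptlc2, of the first step of the pathway, from 81.6 ± 0.883 to 116 ± 1.86 CPM. The calls of the defence (adjusted p = 0.127), promoting (0.0561) and sphingolipid lists (0.103) ended with the stricter filter.

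Sphk1 (ENSMUSG00000061878, chromosome 11, 116530925 to 116536674), the other sphingosine kinase gene, fell from 15 ± 0.891 to 8.45 ± 1.07 CPM (log2 fold change -0.83 ± 0.11, adjusted p = 8.21e-06). Sphk2 (ENSMUSG00000057342, chromosome 7, 45709467 to 45718002), the gene of the inhibitor's target, with 23.5% of its words in other genes, was at 7.18 ± 1.11 and 7.74 ± 1.35 CPM in young and old HSC and did not pass (log2 fold change 0.10 ± 0.14, adjusted p = 0.595). Sphingosine 1-phosphate receptor and signalling genes did not pass as a list. Of 8 tested, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with camera adjusted p = 0.868. Gpx4, the phospholipid peroxidase that blocks ferroptosis, stood at 686 ± 58.9 and 717 ± 31.5 CPM (log2 fold change 0.064 ± 0.053, adjusted p = 0.353). It passed without young replicate 1 (adjusted p = 0.00903), without a filter (0.0478) and with GC and length trends removed (0.00226), and 66.8% of its words recur in other genes. The acyl-CoA synthetase gene Acsl4 did not pass (-0.081 ± 0.085, adjusted p = 0.473). The ferritin heavy chain gene Fth1 rose by a small amount (0.11 ± 0.037, adjusted p = 0.0217), a call that ended without old replicate 1 (adjusted p = 0.0723) and with the stricter filter (0.142). Cdkn1a, a cell cycle inhibitor gene, rose (0.21 ± 0.068, adjusted p = 0.02), a call that ended without old replicate 1 (adjusted p = 0.112), without young replicate 2 (0.0546) and with the stricter filter (0.0599).

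Genes listed as higher in aged HSCs went both ways. Of 40 tested, 11 rose and 11 fell (12 and 12 adjusted over the list alone), with camera adjusted p = 0.577. The median and mean of the list were below 0 (-0.073 and -0.043) while the test's direction was upward, as it was by fry, which tests whether a list moved 1 way on balance (adjusted p = 0.0368). Clu (1.81 ± 0.082, adjusted p = 4.55e-13), Gda (0.63 ± 0.067, adjusted p = 2.44e-07) and Pde4d (0.48 ± 0.045, adjusted p = 4.91e-08) rose, and Vwf, which encodes von Willebrand factor, fell from 21.4 ± 1.27 to 12.5 ± 0.565 CPM (log2 fold change -0.77 ± 0.085, adjusted p = 3.77e-07). Selp (-0.086 ± 0.086, adjusted p = 0.45) and Slamf1 (-0.052 ± 0.13, adjusted p = 0.784) did not pass, and Procr, an HSC surface marker gene, fell (-0.62 ± 0.18, adjusted p = 0.00928), a call that ended with DESeq2 (adjusted p = 0.0546). Levels of Procr were low, 3.69 to 4.10 CPM in young and 2.33 to 2.94 CPM in old libraries. Slamf1 was at 6.18 to 8.63 CPM in young and 7.22 to 7.77 CPM in old libraries. By contrast, the granule protein genes Mpo and Elane, chosen after the values were seen, had means of 11260 and 11144 CPM in young HSC. In old HSC their means were 16797 and 16257 CPM. Whether the sorted cells were mainly HSCs was not tested, so the results for HSC genes hold for the cells as labelled. Genes listed as lower in aged HSCs fell. Of 19 tested, 2 rose and 10 fell (2 and 11 adjusted over the list alone), with camera adjusted p = 0.0234, and adjusted p = 0.109 with an estimated correlation. Cd52 (-0.76 ± 0.046), Ighm (-0.66 ± 0.056) and Sox4 (-0.67 ± 0.06) fell on the log2 scale, and Serpinb1a rose (0.88 ± 0.037). The count of Sox4 is uncertain (54.7% shared words). This call ended without old replicate 2 (adjusted p = 0.0507), without immunoglobulin genes (0.0672) and without genes with shared words (0.0586). HSC identity genes did not pass as a list. Of 32 tested, 4 rose and 12 fell (4 and 12 adjusted over the list alone), with camera adjusted p = 0.126, although they passed downward with the stricter filter (0.0381) and by fry (0.000561). Their members Ly6a (-0.82 ± 0.063, adjusted p = 1.68e-09), Mllt3 (-0.53 ± 0.10, adjusted p = 0.000434) and Gfi1b (-0.58 ± 0.061, adjusted p = 2.02e-07) fell, and Egr1 rose as given above. Of the words of Ly6a, 22.1% recur in other genes. Lymphoid priming genes fell. Of 24 tested, 4 rose and 9 fell (4 and 10 adjusted over the list alone), with camera adjusted p = 0.0354, and adjusted p = 0.166 with an estimated correlation. That call ended without young replicate 3 (adjusted p = 0.0696), old replicate 1 (0.0532), old replicate 2 (0.0736) or immunoglobulin and T cell receptor genes (0.0986).

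The remaining lists did not pass with age. Antioxidant enzyme genes (8 rose and 5 fell of 24 tested, 8 and 5 adjusted over the list alone) lay closest to the threshold, camera adjusted p = 0.0507, and passed with RLE size factors (0.0373) and without young replicate 1 (0.0152), old replicate 2 (0.0271), old replicate 3 (0.0342) or any 1 of the treated libraries (0.0315 to 0.0436). They also passed without immunoglobulin and T cell receptor genes (0.0349) and without genes with shared words (0.0292). Nuclear-encoded genes of oxidative phosphorylation went both ways. Of 75 tested, 12 rose and 21 fell (12 and 21 adjusted over the list alone), with camera adjusted p = 0.492. For transcripts of the mitochondrial genome, 0 rose and 4 fell of 13 tested (0 and 3 adjusted over the list alone), with camera adjusted p = 0.215 (0.031 without young replicate 1). Fatty acid oxidation and PPAR targets (7 rose and 5 fell of 32 tested, 7 and 6 adjusted over the list alone), heat shock proteins (7 rose and 6 fell of 16 tested, 8 and 6 adjusted over the list alone) and p53 targets (10 rose and 4 fell of 31 tested, 11 and 4 adjusted over the list alone) had camera adjusted p of 0.868, 0.385 and 0.263. DNA repair genes (5 rose and 4 fell of 44 tested, 4 and 4 adjusted over the list alone) and chromatin and DNA methylation regulators (5 rose and 7 fell of 39 tested, 5 and 7 adjusted over the list alone) had 0.756 and 0.82. Signs of median, mean and test differed for the fatty acid oxidation, heat shock, S1P receptor and DNA repair lists. The 4 sex-linked genes tested, all on the Y chromosome, rose (4 and 0 adjusted over the list alone), too few members for a list test. Kdm5d rose from 0.0629 ± 0.0759 to 4.45 ± 1.02 CPM and Uty from 5.8 ± 0.485 to 13.9 ± 1.09 CPM. By fry, lists that camera did not call also moved 1 way on balance, upward for S phase (adjusted p = 6.08e-05), p53 targets (7.99e-05), CDK inhibitors (0.00192) and antioxidant enzymes (0.00241), and downward for stromal markers (0.00275), heat shock proteins (0.0105) and T and NK cell markers (0.021). Of the 37 lists, 36 had the 5 tested members required, and 21 passed with age. In other splits of the 6 libraries, which mix the ages, up to 13 lists passed by camera.

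With DESeq2 the numbers that rose and fell with age were 2815 and 1844 (60.4% higher against 49.7% with edgeR). Y-linked transcripts separated every old library from every young one, so no gene's difference with age can be separated from the sex of the donors here.

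**Figure D3:**
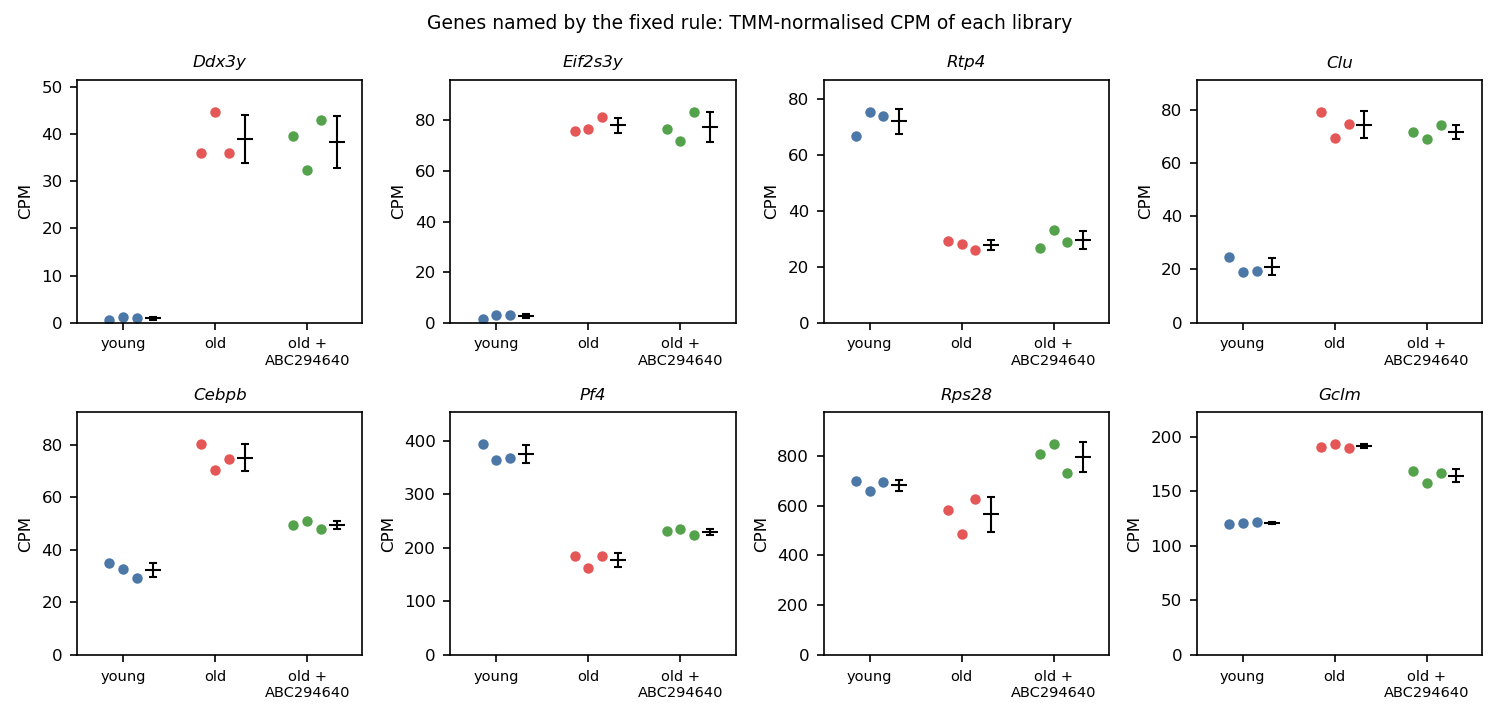
CPM of 8 genes named by the rule in the 9 libraries; points are libraries and the bar is the mean ± SD of 3. Cebpb rose from 32.4 ± 2.8 to 75 ± 5.07 CPM with age and stood at a mean of 49.5 CPM with the inhibitor, and Pf4 fell from 375 ± 16.6 to 178 ± 13 CPM with age and stood at 230.3 CPM with the inhibitor.

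Treated old HSC were compared with untreated old HSC to ask what the SphK2 inhibitor changes. Genes of the cytosolic ribosome and of oxidative phosphorylation were higher with the inhibitor, and inflammatory, immediate early and stress response genes were lower, by small amounts. Each of these list calls was lost with an estimated correlation (adjusted p = 0.106 to 0.356). Rps28, a ribosomal protein gene (ENSMUSG00000067288, chromosome 17, 33819027 to 33824562), rose from 565 ± 71.2 to 796 ± 60.5 CPM (log2 fold change 0.49 ± 0.068, adjusted p = 0.000527). Cebpb, a transcription factor gene of inflammation and granulocyte differentiation (ENSMUSG00000056501, chromosome 2, 167688915 to 167690418), fell from 75 ± 5.07 to 49.5 ± 1.51 CPM (log2 fold change -0.60 ± 0.067, adjusted p = 4.14e-05). In all, 109 genes rose and 61 fell of 14227 tested, with a median absolute log2 fold change of 0.32, and 3 rose and 17 fell by at least 2-fold.

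Chosen in the same way, the 6 largest rises were Rpl37rt, a transcribed processed pseudogene in the annotation (0.60 ± 0.10, adjusted p = 0.00443), Hmga1b (0.56 ± 0.13, adjusted p = 0.0379), the flavin monooxygenase gene Fmo1 (0.52 ± 0.12, adjusted p = 0.0435), Rps28, Rps29 (0.47 ± 0.087, adjusted p = 0.00599) and Sgip1 (0.47 ± 0.084, adjusted p = 0.00516). The 6 largest falls were Crls1, the cardiolipin synthase gene (from 22.4 ± 1.99 to 14.1 ± 2.44 CPM, log2 fold change -0.66 ± 0.11, adjusted p = 0.00277), Cebpb, Yrdc (-0.57 ± 0.10, adjusted p = 0.00516), the interferon-inducible GTPase gene Irgm2 (-0.48 ± 0.12, adjusted p = 0.0451), Tmem165 (from 96.9 ± 3.08 to 71.1 ± 3.27 CPM, log2 fold change -0.44 ± 0.063, adjusted p = 0.000608) and the immunoglobulin gene Ighg2b (from 75.5 ± 4.14 to 57.5 ± 2.56 CPM, log2 fold change -0.39 ± 0.061, adjusted p = 0.00167). Rpl37rt and Hmga1b share 49.1% and 90.5% of their words with other genes, Rps29 29.7%, and Irgm2 overlaps Igtp, which makes these values uncertain. Without treated replicate 2, the calls ended for Rpl37rt (adjusted p = 0.057), Rps29 (0.075), Sgip1 (0.0655), Yrdc (0.0544), Hmga1b (0.335), Fmo1 (0.281) and Irgm2 (0.276). That of Sgip1 also ended without old replicate 2 (0.0524), and that of Hmga1b without treated replicate 1 (0.139), old replicate 2 (0.238) or old replicate 3 (0.148). Fmo1 (0.0526) and Hmga1b (0.0517) lost their calls with the stricter filter. Fmo1 also lost its call without treated replicate 1 (0.111) or 3 (0.0963), old replicate 1 (0.24) or 2 (0.164), or young replicate 2 (0.0532) or 3 (0.0632). Irgm2 lost it without treated replicate 1 (0.216), old replicate 1 (0.0962), 2 (0.245) or 3 (0.0862), or young replicate 2 (0.0519) or 3 (0.0604), and without immunoglobulin and T cell receptor genes (0.0503). Of all genes tested, 15.5% had treated libraries that did not overlap the untreated old ones, against 10% by chance.

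Cytosolic ribosomal protein genes rose with the inhibitor. Of 76 tested, 20 rose and 0 fell (31 and 2 adjusted over the list alone), with camera adjusted p = 4.32e-21, and adjusted p = 0.225 with an estimated correlation. Rps28 was followed by Rpl38 (from 756 ± 102 to 1003 ± 31.1 CPM, log2 fold change 0.41 ± 0.066, adjusted p = 0.00227), Rps26 (0.33 ± 0.059, adjusted p = 0.00516) and Rpl32 (0.26 ± 0.046, adjusted p = 0.00565), and the counts of Rpl38 and Rpl32 are uncertain (42.9% and 46.9% shared words). Old replicate 2 was the lowest of the old libraries for Rps28, Rpl38, Rps26 and Rpl32, and the list passed without it. The share of counts in all ribosomal protein genes was 8.28%, 7.73% and 8.29% in old replicates 1, 2 and 3 and 8.67% on average in treated HSC, and that of pseudogenes, many of them copies of such genes, 1.14% and 1.29% on average. Nuclear-encoded genes of oxidative phosphorylation rose. Of 75 tested, 12 rose and 0 fell (27 and 0 adjusted over the list alone), with camera adjusted p = 1.45e-16, and adjusted p = 0.356 with an estimated correlation. They included the ATP synthase subunit genes Atp5k (0.37 ± 0.066, adjusted p = 0.00498) and Atp5e (0.28 ± 0.053, adjusted p = 0.00656), and Ndufa4 (0.31 ± 0.056, adjusted p = 0.00516) and Cox7b (0.29 ± 0.053, adjusted p = 0.00598) of cytochrome c oxidase. Old replicate 2 was the lowest of the old libraries for these 4 genes as well, and this list too passed without it. Without treated replicate 2 the calls ended for Rps26 (adjusted p = 0.0655), Rpl32 (0.0663), Atp5k (0.057), Atp5e (0.0838), Ndufa4 (0.0663) and Cox7b (0.0566), and without treated replicate 1 for Rpl32 (0.0572), Atp5e (0.0603) and Cox7b (0.0592). Transcripts of the mitochondrial genome rose. Of 13 tested, 2 rose and 0 fell (3 and 0 adjusted over the list alone), with camera adjusted p = 0.000605, and adjusted p = 0.48 with an estimated correlation. This call ended with GC and length trends removed, a setting chosen after seeing the data (adjusted p = 0.594). The mitochondrial genome's whole share of counts was 5.60% ± 0.124 in old and 5.73% ± 0.173 in treated HSC (exact permutation p = 0.3). The list's members that rose were ATP8, of ATP synthase, which overlaps ATP6 on the same strand (from 400.3 ± 35.4 to 550.0 ± 17.6 CPM, log2 fold change 0.46 ± 0.061, adjusted p = 0.000402), and ND4L (0.25 ± 0.058, adjusted p = 0.0334), whose count is uncertain since 98.9% of its words recur in other genes. The ND4L call ended with those trends removed (adjusted p = 0.56) and without treated replicate 1 (0.151) or 2 (0.258), old replicate 2 (0.22) or young replicate 3 (0.0543). Megakaryocyte and platelet markers rose. Of 27 tested, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with camera adjusted p = 0.00347, and adjusted p = 0.106 with an estimated correlation. The member past the threshold was Pf4 (from 178 ± 13 to 230.3 ± 5.7 CPM, log2 fold change 0.37 ± 0.053, adjusted p = 0.000631). For Vwf (0.27 ± 0.089, adjusted p = 0.248) and F2rl2 (0.19 ± 0.077, adjusted p = 0.429) the test was not passed.

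NF-kB and inflammatory genes fell. Of 35 tested, 0 rose and 2 fell (0 and 3 adjusted over the list alone), with camera adjusted p = 0.000367, and adjusted p = 0.106 with an estimated correlation. Cebpb and the chemokine gene Cxcl10 (from 235 ± 5.06 to 197 ± 4.86 CPM, log2 fold change -0.26 ± 0.043, adjusted p = 0.00302) fell, and Tnf (-0.23 ± 0.071, adjusted p = 0.182) and Cxcl2 (-0.17 ± 0.06, adjusted p = 0.297) did not pass. Of the immediate early genes, 0 rose and 2 fell of 27 tested (0 and 4 adjusted over the list alone), with camera adjusted p = 0.00108, and adjusted p = 0.225 with an estimated correlation. These were Jund (-0.27 ± 0.058, adjusted p = 0.023) and Ier5 (-0.37 ± 0.081, adjusted p = 0.0266). The Jund call ended without treated replicate 1 (adjusted p = 0.134) or 3 (0.141) and without old replicate 1 (0.175) or 2 (0.0506). The Ier5 call ended without treated replicate 1 (0.163), 2 (0.0663) or 3 (0.101) and without old replicate 1 (0.193) or 2 (0.0861). The unfolded protein and integrated stress response fell. Of 35 tested, 0 rose and 1 fell (0 and 2 adjusted over the list alone), with camera adjusted p = 0.000506, and adjusted p = 0.106 with an estimated correlation. Cebpb was the member past the threshold. The asparagine synthetase gene Asns (-0.19 ± 0.049, adjusted p = 0.0591) did not pass, but passed with DESeq2 (0.0167), RLE size factors (0.0463), the stricter filter (0.0288), the 2 groups alone (0.021), thinned counts (0.0405) and GC and length trends removed (0.0154), and without young replicate 1 (0.0155) or 2 (0.0488). The amino acid metabolism genes Psat1 (-0.14 ± 0.048, adjusted p = 0.252) and Slc7a5 (-0.19 ± 0.073, adjusted p = 0.38) did not pass.

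Of the genes of ferroptosis defence, 0 rose and 1 fell of 31 tested (0 and 3 adjusted over the list alone). Camera called the list downward (adjusted p = 0.0405, median log2 fold change -0.038), but not with an estimated correlation (adjusted p = 0.189). The call ended without treated replicate 1 (adjusted p = 0.0776) or 3 (0.0738), and without old replicate 1 (0.0856) or 2 (0.0945). The member that fell was Gclm, a subunit of the enzyme that starts glutathione synthesis (from 191 ± 1.95 to 164 ± 5.98 CPM, log2 fold change -0.22 ± 0.044, adjusted p = 0.0124), a call that ended without treated replicate 2 (adjusted p = 0.118) or old replicate 1 (0.0573) or 2 (0.0524). Gsr (-0.16 ± 0.047, adjusted p = 0.141) and Pcbp1 (-0.16 ± 0.044, adjusted p = 0.0992) did not pass, but passed with DESeq2 (0.0291 and 0.00994), the 2 groups alone (0.0363 and 0.0458) and GC and length trends removed (0.0477 and 0.0344), and without young replicate 1 (0.0149 and 0.0195). Gsr also passed without a filter (0.0404). Ferroptosis promoting genes did not pass. Of 32 tested, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.578. Of them, 2 were at an unadjusted p under 0.05, and DESeq2 called 0. Their members of smallest p were Hmgb1 (-0.13 ± 0.058, adjusted p = 0.513, 43.5% shared words) and Cybb (-0.10 ± 0.048, adjusted p = 0.553). Sphingolipid metabolism genes did not pass either. Of 41 tested, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.591. Of these, 2 were at an unadjusted p under 0.05, and DESeq2 called 0. Their members of smallest p were Ormdl2 (0.13 ± 0.046, adjusted p = 0.31, 75% shared words) and Gba2 (-0.24 ± 0.11, adjusted p = 0.513).

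None of the 12 genes fixed for naming in every comparison passed with the inhibitor in edgeR, where 1 had an unadjusted p under 0.05, or in any alternative run, and DESeq2 called 0. Sphk2 was at 7.74 ± 1.35 and 6.35 ± 0.279 CPM in old and treated HSC (log2 fold change -0.28 ± 0.15, adjusted p = 0.621) and Sphk1 at 8.45 ± 1.07 and 7.81 ± 0.972 CPM (-0.12 ± 0.13, adjusted p = 0.871). Slc7a11 (-0.20 ± 0.11, adjusted p = 0.626), Tfrc (-0.099 ± 0.07, adjusted p = 0.76), Gpx4 (0.025 ± 0.053, adjusted p = 0.954), Acsl4 (-0.04 ± 0.087, adjusted p = 0.954) and Fth1 (0.015 ± 0.037, adjusted p = 0.968) did not pass. Nor did Procr (0.34 ± 0.19, adjusted p = 0.652), Slamf1 (0.059 ± 0.14, adjusted p = 0.959), Selp (-0.014 ± 0.088, adjusted p = 0.987) and Cdkn1a (-0.015 ± 0.069, adjusted p = 0.982).

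**Figure D4:**
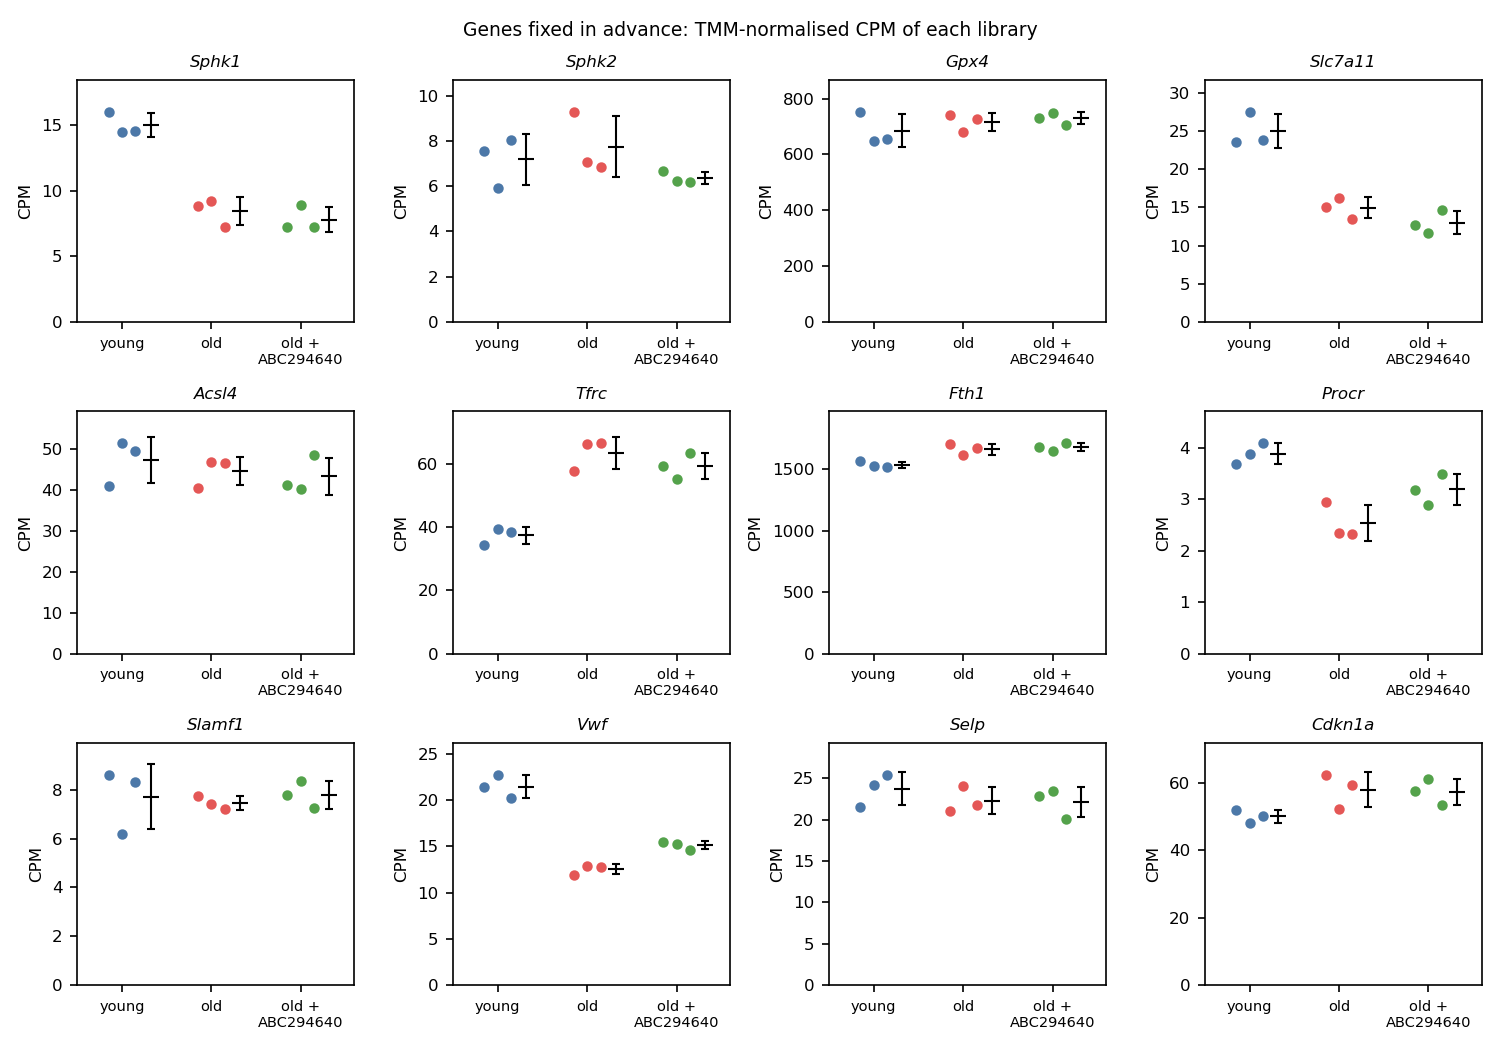
CPM of the 12 genes named in every comparison in the 9 libraries; points are libraries and the bar is the mean ± SD of 3. Sphk1 stood at means of 15, 8.45 and 7.81 CPM in young, old and treated old HSC, and Slc7a11 at 25, 15 and 13.

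Of the 36 lists tested, 8 passed with the inhibitor, against up to 6 in splits of the 6 libraries that mix the groups. The other 28 lists did not pass (camera adjusted p from 0.0514 to 0.978). With an estimated correlation none of the 8 passed. By fry, the calls also ended for cytosolic ribosomal proteins (adjusted p = 0.0571), immediate early genes (0.0571), oxidative phosphorylation (0.137) and mitochondrial genome transcripts (0.208). Closest were interferon-stimulated genes. Of 40 tested, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.0514. Of these 40 genes, 10 were at an unadjusted p under 0.05 in edgeR, and DESeq2 called 0. The smallest p belonged to Xaf1 (0.22 ± 0.059, adjusted p = 0.0959) and Mx1 (-0.49 ± 0.17, adjusted p = 0.256), and Xaf1 passed with GC and length trends removed (adjusted p = 0.0328). The list passed upward without young replicate 1 (0.0442) or treated replicate 2 (0.0361), by fry (0.0114), with GC and length trends removed (0.0345), and without immunoglobulin and T cell receptor genes (0.0445), genes with shared words (0.0248) or sex chromosome genes (0.05 after rounding). Mast cell and basophil markers did not pass (0 rose and 0 fell of 12 tested, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0629), with 5 members at an unadjusted p under 0.05 in edgeR and 0 called by DESeq2. They passed without treated replicate 2 (0.033), without genes with shared words (0.0353), with the stricter filter (0.013), with the 2 groups alone (0.0293) and by fry (0.042), by which S phase genes passed too (0.042). Of the granulocyte and monocyte markers 1 member, Chil3, fell (0 rose and 1 fell of 31 tested, 2 and 4 adjusted over the list alone, camera adjusted p = 0.159), and the list passed downward without old replicate 2 (0.00349), without treated replicate 2 (0.0184) and with GC and length trends removed (4.6e-05). Single members past the threshold in other lists that did not pass were Pola2 and Car1, which rose, and Hdac2 and Jchain, which fell, all named after their values were seen. HSC identity genes (0 rose and 0 fell of 32 tested, 0 and 0 adjusted over the list alone, camera adjusted p = 0.297), genes listed as higher in aged HSCs (0 rose and 0 fell of 40 tested, 0 and 0 adjusted over the list alone, camera adjusted p = 0.791) and genes listed as lower in aged HSCs (0 rose and 0 fell of 19 tested, 0 and 0 adjusted over the list alone, camera adjusted p = 0.578) did not pass, with 3, 1 and 2 members at an unadjusted p under 0.05 and 0 called by DESeq2. Signs of median, mean and test differed for the DNA repair, T and NK cell, lymphoid priming and glycolysis lists.

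The number of genes called with the inhibitor depended on single libraries: the 109 that rose became 52 without old replicate 1, 40 without old replicate 2, 31 without treated replicate 1, 17 without treated replicate 2 and 175 without young replicate 1, and the 61 that fell became 39, 37, 38, 31 and 111. With GC and length trends removed, chosen after seeing the data, 128 rose and 121 fell (51.4% higher against 64.1%).

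Set against age, the inhibitor's changes ran mostly the other way, which the shared old libraries favour by themselves. Of the 5606 genes called with age, 3717 (66.3%) had an inhibitor change of opposite sign, called or not. Of the 142 genes called in both comparisons, 126 had opposite signs, 77 of them lower with age and higher with the inhibitor and 49 the reverse, and 16 had the same sign. Cebpb, Crls1, Tmem165, Cxcl10, Gclm and Ighg2b rose with age and fell with the inhibitor. Pf4, Rps28, Rpl38, ATP8, Rps26 and Sgip1 fell with age and rose with the inhibitor. Irgm2 fell in both. The sizes were unequal: Pf4 fell by 1.08 on the log2 scale with age and rose by 0.37 with the inhibitor, and Cebpb rose by 1.21 and fell by 0.60.

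The 6 genes with the largest opposite changes were immunoglobulin variable genes, all higher with age and lower with the inhibitor. All 6 were at 0.249 CPM or less in every young and treated library. A gene counted mainly in the shared old libraries has opposite signs by construction, so these signs show no effect of age or inhibitor by themselves. Ighv10-3 and Ighv7-3 were at 0.845 ± 0.252 and 0.822 ± 0.129 CPM in old HSC and had no count in treated HSC, at least 15.3-fold and 14.9-fold lower against a floor of 3 counts over the group. Igkv6-20 fell from 5.25 ± 0.761 to 0.153 ± 0.0942 CPM (adjusted p = 3.15e-07), Igkv6-25 from 1.42 ± 0.279 to 0.0171 ± 0.0297 CPM, Igkv16-104 from 2.19 ± 0.496 to 0.057 ± 0.00519 CPM and Igkv3-10 from 2.29 ± 0.186 to 0.0719 ± 0.0776 CPM. At least 32.0% of the words of each of these genes except Igkv16-104 recur in other genes, so that their counts are uncertain.

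Both comparisons share the 3 old HSC libraries, which by itself gives opposite signs. Across 14227 genes, which are not independent replicates, the correlation of the log2 fold changes was -0.207 and the covariance -0.0461. In 20 simulations with no effect in any group these were -0.51 and -0.0215 on average, with a lowest covariance of -0.0226. The observed covariance differed from the simulated mean by -0.0246. The covariance moved to -0.0108 with the stricter filter, -0.0258 without genes with shared words, and -0.0982, -0.146 and -0.0918 without old replicate 1, 2 or 3. It was -0.0721 without treated replicate 2, and -0.367 with DESeq2 over all its genes. The draws were analysed in the same ways, over the 14227 genes. The observed covariance was then -0.0108, -0.0258, -0.0639, -0.107, -0.0596, -0.0463 and -0.0455 in the same order. The lowest simulated values were -0.00647, -0.022, -0.0371, -0.0393, -0.0364, -0.0248 and -0.0256 (10 draws for DESeq2). Without immunoglobulin and T cell receptor genes the observed covariance was -0.0329 and the lowest simulated value -0.02245. The difference from the simulated mean was then -0.0115. With no age or inhibitor effect to call, the simulations called 0.3 genes in both with opposite sign on average and at most 2, a count not comparable with 126. Independent lists of the observed sizes would share 21.6 genes lower with age and higher with the inhibitor, 12.0 the reverse, and 21.4 and 12.1 that rose or fell in both, against 77, 49, 10 and 6 observed. With 3 old libraries no split leaves 2 on each side, so part of the excess may come from the shared libraries. The draws were independent between libraries and between genes, so a deviation common to the 3 old libraries was not simulated. The 126 genes became 75 without old replicate 1, 56 without old replicate 2, 58 without treated replicate 1 and 40 without treated replicate 2, and 70 without genes with shared words, a setting chosen after seeing the data.

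**Figure D5:**
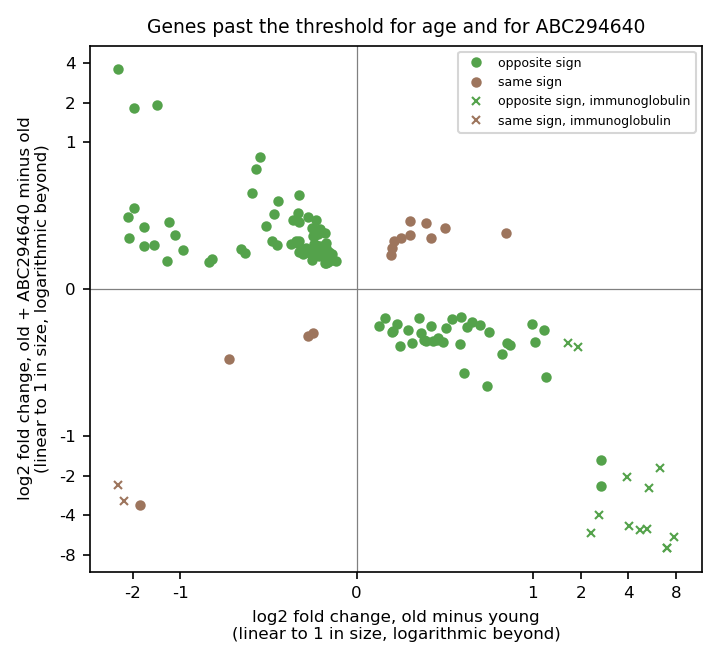
Log2 fold change with age (horizontal) against log2 fold change with the inhibitor (vertical) for the 142 genes called in both, on axes linear near 0 and logarithmic beyond; crosses are immunoglobulin genes. In the quadrants of opposite sign lie 126 genes, and 16 lie in those of equal sign.

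Treated old HSC were also compared with young HSC, which asks how far from the young state the treated cells lay. Against young HSC, 2722 genes rose and 2633 fell of 14227 tested, with a median absolute log2 fold change of 0.44. The interferon-stimulated genes were lower. Of 40 tested, 0 rose and 35 fell (0 and 36 adjusted over the list alone), with camera adjusted p = 2.25e-29. Erythroid markers were lower. Of 25 tested, 2 rose and 20 fell (2 and 21 adjusted over the list alone), with camera adjusted p = 2.53e-10. Mitosis genes were higher. Of 32 tested, 26 rose and 0 fell (26 and 0 adjusted over the list alone), with camera adjusted p = 1.42e-06. The unfolded protein and integrated stress response was higher. Of 35 tested, 22 rose and 1 fell (25 and 1 adjusted over the list alone), with camera adjusted p = 4.46e-06. These 4 of the 16 lists that passed (12 upward and 4 downward) also passed with an estimated correlation (adjusted p = 0.000344, 0.00537, 0.012 and 0.0164).

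The other 12 lists that passed had adjusted p from 0.0677 to 0.299 with an estimated correlation. Upward these were granulocyte and monocyte markers (19 rose and 6 fell of 31 tested, 19 and 7 adjusted over the list alone), glycolysis (15 rose and 0 fell of 22 tested, 15 and 2 adjusted over the list alone), lysosome and autophagy (22 rose and 4 fell of 43 tested, 22 and 4 adjusted over the list alone), immediate early genes (15 rose and 2 fell of 27 tested, 16 and 2 adjusted over the list alone), iron handling (14 rose and 6 fell of 34 tested, 14 and 8 adjusted over the list alone), proteasome (18 rose and 1 fell of 31 tested, 19 and 1 adjusted over the list alone), ferroptosis promoting (11 rose and 3 fell of 32 tested, 11 and 4 adjusted over the list alone), B cell markers (5 rose and 3 fell of 17 tested, 5 and 3 adjusted over the list alone), antioxidant enzymes (7 rose and 3 fell of 24 tested, 8 and 3 adjusted over the list alone) and cholesterol and fatty acid synthesis (13 rose and 2 fell of 29 tested, 14 and 2 adjusted over the list alone). Downward they were megakaryocyte and platelet markers (2 rose and 15 fell of 27 tested, 2 and 16 adjusted over the list alone) and genes listed as lower in aged HSCs (2 rose and 9 fell of 19 tested, 2 and 9 adjusted over the list alone). The call of the last of these ended without immunoglobulin genes (adjusted p = 0.115), without genes with shared words (0.118), and without old replicate 2 (0.0552) or 3 (0.0546), young replicate 3 (0.0515) or treated replicate 1 (0.052), 2 (0.0797) or 3 (0.0675). B cell markers ended without immunoglobulin genes (0.679), and the antioxidant (0.188), cholesterol (0.188), ferroptosis promoting (0.122, and 0.0625 without sex chromosome genes) and proteasome lists (0.15) with the stricter filter. Cytosolic ribosomal protein genes did not pass (10 rose and 11 fell of 76 tested, 7 and 9 adjusted over the list alone, camera adjusted p = 0.788), nor did ferroptosis defence (11 rose and 4 fell of 31 tested, 11 and 4 adjusted over the list alone, camera adjusted p = 0.129, 0.0345 without genes with shared words) and sphingolipid metabolism (15 rose and 5 fell of 41 tested, 16 and 6 adjusted over the list alone, camera adjusted p = 0.0594, 0.03 to 0.0484 without old replicate 1 or 3, treated replicate 3, genes with shared words, or immunoglobulin and T cell receptor genes). Oxidative phosphorylation genes (19 rose and 3 fell of 75 tested, 19 and 3 adjusted over the list alone, camera adjusted p = 0.0707) passed upward without young replicate 1 (0.00984), any 1 old library (0.0273 to 0.0484), or treated replicate 1 (0.0359) or 3 (0.0332), and without genes with shared words (0.0119) or immunoglobulin and T cell receptor genes (0.0447). The other lists had camera adjusted p up to 0.904, and lymphoid priming passed without young replicate 2 (0.0295), sex chromosome genes (0.0446) or genes with shared words (0.0357), with the stricter filter (0.00298) and with GC and length trends removed (0.0474). Stromal markers passed without treated replicate 3 (0.0471) or genes with shared words (0.0472). Signs of median, mean and test differed for the lists of genes higher in aged HSCs, B cell markers, fatty acid oxidation, chromatin, DNA repair, heat shock and p53 targets.

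Sphk1 was lower in treated than in young HSC (-0.95 ± 0.12, adjusted p = 1.83e-06), as were Slc7a11 (-0.93 ± 0.099, adjusted p = 2.84e-07) and Vwf (-0.51 ± 0.083, adjusted p = 7.56e-05). Tfrc (0.67 ± 0.071, adjusted p = 3.16e-07), Fth1 (0.13 ± 0.037, adjusted p = 0.0111) and Cdkn1a (0.19 ± 0.068, adjusted p = 0.0309) were higher. The Fth1 call ended without treated replicate 3 (adjusted p = 0.051) and with the stricter filter (0.147). The Cdkn1a call ended without treated replicate 1 (0.0623) or 2 (0.112) or young replicate 2 (0.0888) or 3 (0.0556), with the stricter filter (0.129) and with GC and length trends removed (0.0592). Procr (-0.28 ± 0.17, adjusted p = 0.215), Sphk2 (-0.18 ± 0.15, adjusted p = 0.349), Acsl4 (-0.12 ± 0.086, adjusted p = 0.282), Gpx4 (0.089 ± 0.053, adjusted p = 0.194), Selp (-0.10 ± 0.086, adjusted p = 0.384) and Slamf1 (0.0074 ± 0.13, adjusted p = 0.971) did not pass, although without young replicate 1 Gpx4 (0.00373) and Acsl4 (0.0309) did, and Gpx4 also without a filter (0.00997) and with GC and length trends removed (0.0199). Chosen in the same way, the 4 largest rises were Igkv15-103, from no count in young HSC to 11.3 CPM (at least 239-fold), Igkv6-23 (from 0.0138 ± 0.0239 to 12.5 ± 0.329 CPM), Igkv1-110 (from 0.0307 ± 0.0532 to 14.6 ± 0.411 CPM) and Igkv10-96 (from 0.0317 ± 0.0275 to 10.6 ± 0.702 CPM). The 4 largest falls were Igkv8-19 (from 12.9 ± 0.149 to 0.0171 ± 0.0297 CPM), Igkv19-93 (from 20.5 ± 2.82 to 0.504 ± 0.304 CPM), Igkv2-137 (from 10.7 ± 0.339 to 0.609 ± 0.268 CPM) and Igkv4-59 (from 14.5 ± 0.268 to 3.19 ± 0.582 CPM), and reads shared with other genes make these values uncertain except those of Igkv15-103 and Igkv19-93.

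Treated libraries carried Y-linked transcripts as the old ones did, so that sex and age differ together in this comparison too. DESeq2 called 2708 higher and 1835 lower.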

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

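Alternatives added after seeing the data are those without immunoglobulin, shared-word or sex chromosome genes, with thinned counts, and with GC and length trends removed. Of 3470 results for named genes under the alternatives, 3374 kept their direction and side of the threshold, 66 were no longer past it, 30 newly passed it and 0 reversed, and 148 of the 179 pairs of a gene and a comparison kept theirs under every alternative that tested them, from 128 tested without genes with shared words to all 179. Of 2157 results for gene lists, 2011 kept theirs, 76 were no longer past and 70 newly past. Of 211 results for counts and overlaps, 179 kept theirs, 31 moved and 1 was no longer past. With a threshold of at least 2-fold, 225 genes were higher and 953 lower in old than in young HSC, 3 and 17 with the inhibitor, and 211 and 1053 in treated old against young HSC. DESeq2 called 1844 lower with age. No filter gave 219 higher and 114 lower with the inhibitor, the 2 groups alone 164 and 96, and removal of GC and length trends 121 lower. The stricter filter gave 1732 lower in treated old against young HSC, with fewer genes tested. Without genes with shared words, 70 genes changed with age and inhibitor with opposite sign, with fewer genes tested. The cause of the other differences was not tested.

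Leaving out 1 library gave 17 (treated replicate 2) to 175 (young replicate 1) genes higher and 31 to 111 lower with the inhibitor, by the same libraries, and 40 to 182 with opposite sign, again by the same ones. With an estimated correlation 6 lists passed with age, 0 with the inhibitor and 4 for treated old against young HSC, and fry gave 30, 7 and 29, where it ended 4 of the 8 calls with the inhibitor. Correlations of same-numbered libraries ran from -0.0808 to 0.132, with 1 of 9 over 0.1. Whether the numbers pair the libraries stays open. Between young and old HSC every library correlated best with its own number (0.0628, 0.132 and 0.0636), a hint from the data and not the design, and in the other comparisons this did not hold. With the replicate number as a block, 128 genes were higher and 67 lower with the inhibitor, 2799 and 2783 with age, 2777 and 2578 for treated old against young HSC, and 142 of opposite sign. The ferroptosis defence list with the inhibitor (adjusted p = 0.0501) was the 1 list call that the block changed. In the simulations, 49.3% of the genes with the smallest simulated change were recovered for age and 31.3% for the inhibitor, and 67.3% and 44.7% of those at 5 CPM or more. Other depths were not simulated.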

Other observations

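Chosen after the result was seen were both tests of shared reads, the simulated draws under other settings, the test of the immunoglobulin share, the test of immunoglobulin variable genes, and the genes named in the next paragraph.

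Constant genes of class-switched antibodies, whose transcripts mark plasma cells, were in no fixed list and had no test as a group. Of them 4 were tested, Igha, Ighg2b, Ighg2c and Ighg3, and each rose with age. Igha rose from 34.4 ± 2.09 CPM in young to 110.1 ± 6.48 in old HSC (log2 fold change 1.67 ± 0.066, edgeR adjusted p = 5.21e-14) and stood at 85.4 ± 6.56 with the inhibitor (-0.37 ± 0.062, adjusted p = 0.00311). Ighg2c rose from 33.1 ± 2.06 to 161 ± 8.96 CPM with age and stood at 139 ± 7.81 with the inhibitor, which did not pass (-0.21 ± 0.056, adjusted p = 0.0798). Ighg2b stood at 19.7 ± 1.16, 75.5 ± 4.14 and 57.5 ± 2.56 CPM, and Ighg3 at 0.0470 ± 0.0461, 6.03 ± 0.857 and 4.63 ± 0.675 CPM. Kit, a receptor gene of stem and progenitor cells, was at 119 ± 4.56, 113 ± 2.80 and 117 ± 1.68 CPM and passed in none of the 3 comparisons.

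Old and young HSC differed in 5606 genes. Shared reads are argued against as the main cause, since 16.3% of these genes had shared words against 14.7% of all genes tested, and so are GC content and transcript length, since 91.7% of the calls stayed with those trends removed. The sex of the donors stays open: of 4 X-linked genes that escape inactivation, 2 were higher in young HSC (Kdm6a, log2 fold change -0.56 ± 0.079, and Kdm5c, -0.26 ± 0.079), between the bounds set beforehand. Of the calls, 5365 lie on autosomes, and the design holds no libraries of 1 apparent sex at both ages, so that age and sex cannot be told apart for them. Age itself stays among the open explanations and was not tested apart from sex. Nor were changes within cells told apart from changes in the mix of sorted cells. Mpo was at 11260 ± 475 CPM in young and 16797 ± 194 CPM in old HSC.

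Between treated and untreated old HSC, 126 genes differed against their direction with age. Chance shared through the old libraries with no effect is argued against as the whole cause, since the covariance of -0.0461 lay below the lowest simulated value of -0.0226, as it did in each of 8 other settings run on the simulated draws, the nearest being -0.0258 against -0.022 without genes with shared words, although part of the excess may come from those libraries. Immunoglobulin genes are argued against as most of the 126, since they made up 10.3% of them, against 0.65% of all genes tested. Without immunoglobulin and T cell receptor genes, 106 genes had opposite signs. The covariance then differed from the simulated mean by -0.0115, against -0.0246 with them. This difference was smallest without genes with shared words (-0.00519) and with the stricter filter (-0.00557). It was largest without old replicate 2 (-0.07135). Other transcripts of B cells and plasma cells, such as Jchain among the 126, were not counted, so such cells stay open as a cause. Shared reads stay open, since 47.6% of the 126 had shared words, against 41.2% of the inhibitor's calls and 14.7% of all genes, and a fit without such genes gave 70 genes. An effect of the inhibitor on old HSCs is a hypothesis that these tests leave open.

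Immunoglobulin variable genes varied little within groups. Over those with at least 20 counts in a pair of libraries (20 to 84 genes a pair), the highest chi-square per degree of freedom between libraries of a group was 1.89, and the lowest between groups was 8.79. The chi-square takes reads as independent molecules, which amplified reads without molecular identifiers are not. Over all genes the chi-square per degree of freedom ran from 2.23 to 8.36 within groups, which overlaps the 3.51 to 12.0 between old and treated old libraries. Between young libraries and old or treated old ones, the lowest value over the variable genes was 80.4. A candidate explanation is that the libraries of a group were drawn from 1 pool of cells. Separate mice would give these values only with antibody repertoires alike within each group and unlike between groups. The values argue against separate mice whose repertoires differed within a group as much as between groups. With 1 pool per group, the p-values for age and inhibitor would measure technical spread only. No biological explanation was tested.

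With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many results in each of the 7 counts. The real and highest other values were 5606 and 0 genes and 21 and 13 lists with age, 170 and 0 genes and 8 and 6 lists with the inhibitor, 5355 and 0 genes and 16 and 12 lists for treated old against young HSC, and 126 and 0 genes of opposite sign. The other splits mix the groups, so the difference between groups enters their spread, and the 0 genes there carry little weight.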
